A study of Homo sapiens with 11 samples.

How the data were processed

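Chromatin accessibility was measured by ATAC-seq in 11 samples of 4 established human cell lines: 2102EP (embryonal carcinoma), VM-CUB-1 (urothelial carcinoma), Caki-1 (renal cell carcinoma) and DU-145 (prostate cancer). Cells had been exposed for 16 h to a drug at its EC50 or to the solvent DMSO. Every combination of line and treatment was a single library, so there were no replicates within a line.

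The submitters' processing notes and the column headers give hg38 as the genome build; the aligner, the peak caller, the scaling of the libraries and their versions are not given in the sources used here. The authors deposited 2 tables of regions made by merging the peaks of their libraries, the first for LAK31 and DMSO in all 4 lines (224159 regions, 8 libraries) and the second for 2102EP with all 4 drugs and DMSO (166579 regions, 5 libraries). Per the file headers, each region carries for every library an average signal and a peak height, a mark for a called peak, the genes nearby with the distance to their start, and counts of CpG islands and promoters. No average lay between 0 and 1; whether empty bins had been left out of the averages, which would overstate low values, was not tested. The 49938 regions with the same ends in both tables held identical averages for the 2102EP libraries with DMSO and LAK31. The authors' deposited table for the 4 lines also holds a shrunken fold change of LAK31 over DMSO per line, read here as log2 because both signs occur around 0; its base and tool are not stated, and it was used only as a value beside the ratios computed here. Read counts per library were not in the sources used here, so the depth is unknown and no counting interval or floor was given; the number of called peaks and the median signal stand in the report instead.

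The average signal was put on a log2 scale after adding the 10th percentile of the non-zero averages (1.625 in the first table, 5 in the second). Regions with a mean signal at or above the 25th percentile were kept, 168134 of the first table and 124941 of the second over all 5 libraries; single pairs used the same percentile over their own 2 libraries. The median region was 368 bp long in the first table and 353 bp in the second. A gene's promoter region was the region assigned to it nearest its start, at most 1000 bp away, which gave 22604 genes in the first table and 20855 in the second. Of the 36466 gene names in the first table, 28366 were current RefSeq symbols, and 29915 matched when synonyms were allowed. In the second table the corresponding numbers were 35406, 27623 and 29149.

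LAK31 was compared with DMSO across the 4 lines with limma 3.58.1, cell line as a block and treatment as the tested term, with an intensity trend in the empirical Bayes step (4 pairs, 3 residual degrees of freedom, 27.5 prior degrees of freedom). P values were adjusted by the Benjamini-Hochberg method at 5%. Pairing by line was checked with the correlation, across regions, of each library's deviation from the mean of its treatment: between the libraries of a line it was 0.879 in 2102EP, 0.745 in VM-CUB-1, 0.789 in Caki-1 and 0.819 in DU-145, against at most 0.126 with a library of another line. Deviations from a treatment mean cancel out over the 4 lines, so a high value within a line lowers those with other lines by construction. The same limma model compared each line with the mean of the other 3, with 2 libraries per line. Called regions were compared with all tested regions by the class that the table gives them, with Fisher's exact test; the share of a class among tested regions with the same mean signal (20 bins) was added after seeing the data. Single pairs (LAK31 in each line, each drug in 2102EP) had 1 library against 1 and were described without p values, by the number of regions at least 2-fold higher or lower and the median log2 ratio. The overlap of drugs in 2102EP was set beside that of simulated unchanged libraries sharing the DMSO library (10 draws), with noise taken from the spread of the MZ-1 ratios, which also holds any change with MZ-1.

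The 18 gene lists held 456 genes in 466 entries: pluripotency and embryonal carcinoma, urothelial, renal, prostate, germ cell and cancer testis, HDAC inhibitor response and cell cycle arrest, AP-1 and immediate early, apoptosis, neuronal and REST target, trophoblast and germ layer, epithelial and mesenchymal, HDAC and bromodomain regulators, MYC and BET dependent, cell cycle and proliferation, heat shock and proteostasis, immune and interferon, metallothionein, and housekeeping. Across lines they were tested on promoter regions with limma's camera, with a preset and with an estimated correlation. In single pairs a list's median was placed among 10000 random lists of the same size matched on signal in 20 bins. A second placement also matched them on touching a CpG island. All 18 lists were placed in every pair and mainly the outermost percentiles are named, so some would be extreme by chance. The lists, the model, the filter, the pseudocount, the thresholds, the alternatives named first below and the rule for named genes were fixed before the data were examined.

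Genes were named by that rule. Across lines it took the 10 regions with the largest mean log2 ratio in each direction, 1 per gene, among those past the threshold and changed the same way in all 4 lines. In each single pair it took the 5 genes with the largest ratio in each direction among promoter regions with a signal at or above the median. Each list gave up to 4 members with the largest absolute ratio, and a fixed set including CDKN1A, POU5F1, NANOG, SOX2, MYC, HEXIM1 and HDAC1 was added wherever measured; CDKN1A and POU5F1 had no promoter region within the distance. Results for some of the genes taken are not reported here. Of the genes so taken, uncharacterised loci and immune receptor segments are mostly left unnamed in the text.

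The model was tested on simulated data with changes set into 50 regions each: 38 were recovered at a log2 ratio of -2, 3 at -1, 11 at 1 and 49 at 2, with 4 calls among unchanged regions. The simulated noise followed the intensity trend in every region and each change was the same in all lines. The model may therefore do worse on the real data than in this test. Alternatives were other pseudocounts (0.25 and 4 times the main), no filter, libraries centred on their median, quantile normalisation, scaling to housekeeping promoters, peak height in place of the average, no cell line block, leaving out each line, no intensity trend, autosomal regions alone, all regions of a gene in place of its promoter region, and for the lines DMSO libraries alone. An estimated correlation in the set test and a restriction to regions with a peak called in every line were added after seeing the data. Count models such as edgeR or DESeq2 were not used, since the tables hold no counts. No motif analysis was made, because only gene positions and no sequence were at hand. The work used R 4.3.3 with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.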

Results

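ATAC-seq reads out the DNA that a transposase can reach, so a higher signal over a region stands for more open chromatin. The series compares the epigenetic agent LAK31, which the submitted file name places among histone deacetylase (HDAC) inhibitors, with DMSO in 4 urological cancer lines. 2102EP cells were also given romidepsin or quisinostat, both HDAC inhibitors, or MZ-1, a degrader of BET bromodomain proteins. Each line and treatment had 1 library (11 samples, 16 h), with no replicates within a line. The depth is unknown; the peaks called per library in the table of 4 lines numbered 115821 with DMSO and 107451 with LAK31 in 2102EP, 63475 and 60924 in VM-CUB-1, 81544 and 81766 in Caki-1, and 63655 and 76497 in DU-145. In the table of 2102EP drugs, 77371 peaks were called with romidepsin, 42164 with quisinostat and 73523 with MZ-1, against 116699 with DMSO and 107771 with LAK31. The median signal of the same 5 libraries was 14.9, 10.2, 14.0, 23.6 and 19.7.

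The lines differed at promoters of lineage genes, which served to check the labels. In 2102EP the promoter region of NANOG, a pluripotency factor (hg38, chromosome 12, 7787521 to 7788011), was higher than in the mean of the other lines by a log2 ratio of 4.15 (SE 0.57, 2 libraries per line, adjusted p = 4.66e-07). DPPA2, also active in pluripotent cells, was higher there by 5.49 (SE 0.49, adjusted p = 5.90e-10), while SOX2 had a log2 ratio of 0.10 and was not past the test. In VM-CUB-1 the promoter of the basal keratin KRT5 was higher by 4.95 (SE 0.50, adjusted p = 4.24e-08). In Caki-1 that of PAX8, a transcription factor of the kidney lineage, was higher by 4.21 (SE 0.53, adjusted p = 9.76e-07).

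Grouped by list, 15 of the 20 tested promoter regions of the pluripotency and embryonal carcinoma list were higher in 2102EP and 2 lower (median log2 ratio 3.16, camera adjusted p = 9.69e-09). TDGF1 (4.72) and LIN28B (4.01) were among them. Of 19 regions of germ cell and cancer testis genes, 13 were higher and 2 lower in 2102EP (median 2.52, adjusted p = 9.97e-05), with DDX4 at 3.55 and SYCP3 at 3.53. With an estimated correlation neither list passed (adjusted p = 0.592 and adjusted p = 0.461). The urothelial list had 4 higher and 1 lower of 13 regions in VM-CUB-1 (median 0.20, adjusted p = 0.00291, and adjusted p = 0.592 with an estimated correlation). The 4 higher regions were all at keratin genes, with KRT6A and KRT17 both higher by 3.80. The lower one was at PPARG (-1.26, limma adjusted p = 0.0359), and GATA3 was at -1.05 and not past the test. The uroplakin gene UPK1B of this list was higher in 2102EP, by 4.21. Epithelial and mesenchymal genes had 10 higher and 3 lower of 24 in VM-CUB-1 (adjusted p = 0.000388) and 7 higher and 11 lower in Caki-1 (adjusted p = 0.00113), with adjusted p = 0.942 for both with an estimated correlation. CDH1, the epithelial cadherin, was higher in VM-CUB-1 by 1.95 and lower in Caki-1, at -4.06, whereas the intermediate filament gene VIM was at -3.32 and 1.91. The renal list in Caki-1 (3 higher and 2 lower of 12, adjusted p = 0.990) and the prostate list in DU-145 (2 higher and 3 lower of 11, adjusted p = 0.502) were not past the test, although the kidney cadherin CDH16 was higher in Caki-1 by 3.05. The housekeeping list, which marks no lineage, passed in DU-145 (11 higher and 0 lower of 28, adjusted p = 0.0398, and adjusted p = 0.947 with an estimated correlation). In 2102EP it had 1 higher and 15 lower (adjusted p = 0.0647). Over all regions, 58884 were higher and 49126 lower in 2102EP, 19965 and 30933 in VM-CUB-1, 36483 and 24927 in Caki-1, and 27351 and 32208 in DU-145; the spread between the libraries of a line includes its response to LAK31.

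Across the 4 lines, a region in the first part of MYH9, a non-muscle myosin gene (hg38, chromosome 22, 36385911 to 36386680, 1772 bp downstream of the start), fell with LAK31 from a mean signal of 82.1 to 9.90. The log2 ratio was -3.04 (SE 0.36, n = 4 pairs, adjusted p = 0.000229). Each SE is limma's, drawn towards the intensity trend over regions, and does not give the spread of the 4 pairs. The SD over the 4 lines was 0.89 at this region and 1.18 at that near TNFSF9 below. A region 699 bp downstream of the start of STAT3, a transcription factor of cytokine signalling (chromosome 17, 42387654 to 42387955), fell by 2.65 on the log2 scale (SE 0.38, adjusted p = 0.00190) and had a mean signal of 53.1 with DMSO. In the other direction, a region within ROR2, a Wnt receptor gene (chromosome 9, 91796495 to 91797152), rose by 2.75 (SE 0.39, adjusted p = 0.00190), from 5.64 to 52.0. A region near TNFSF9, which encodes a ligand of T cell costimulation (chromosome 19, 6539304 to 6539953), rose by 2.59 (SE 0.39, adjusted p = 0.00277), from 13.9 to 72.3. The promoter region of the secretoglobin gene SCGB2A1 (chromosome 11, 62208427 to 62208853), 28 bp upstream of its start, rose from 3.52 to 26.1 (log2 ratio 2.29, SE 0.44, adjusted p = 0.0121).

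In all, 711 regions rose and 1104 fell among 168134 tested (limma, adjusted over all regions), and 688 and 1081 of these moved the same way in all 4 lines. The named regions that rose also lay in CHMP4B (2.50), SPAG16 (2.48), CERS4 (2.46), HTR1E (2.34) and LOC401191 (2.55), upstream of INPP4B (2.34; chromosome 4, 142851272 to 142851542) and in LOC105375199 (2.29). Some of the named rises start from DMSO signals of 0, so their size depends on the pseudocount. LOC401191 was at 0 in Caki-1 and DU-145 with DMSO, and its mean ratio ran from 1.40 to 3.71 over the alternatives. HTR1E was at 0 in 2102EP and Caki-1, with 1.34 to 3.41. The named regions that fell lay within 1000 bp of the starts of SPAG9 (-2.66), RNF168 (-2.63), LOC105369141 (-2.73) and LOC105371893 (-2.87). They also lay inside ELOVL5 (-2.74), ACTN4 (-2.69), GOSR1 (-2.51) and the histone demethylase gene KDM4B (-2.51). The class that the table marks as promoter reaches up to 8160 bp from a gene start, wider than the promoter regions of single genes used elsewhere. It made up 65.0% of the regions that fell and 26.7% of those tested (Fisher's exact test, odds ratio 5.19, adjusted p = 1.78e-156). CpG islands were touched by 46.7% of the regions that fell, 0.422% of those that rose and 13.7% of those tested. These tests were not matched on signal, and the ratio changed with signal: from the lowest to the highest quintile the median went from 0.46 to -0.70 in 2102EP, 0.38 to -0.56 in Caki-1, 0.10 to 0.04 in DU-145 and 0 to -0.20 in VM-CUB-1. Among tested regions with the same signal as those that fell, 39.9% were of the promoter class and 25.2% touched an island. Regions outside genes and promoters made up 42.6% of those that rose against 29.4% of those tested (Fisher's exact test, odds ratio 1.79, adjusted p = 7.29e-14). Of the regions that fell, 350 (31.7%) lay 500 to 2000 bp downstream of a gene start, a position held by 4.48% of the tested regions. The median DMSO signal was 55.2 for regions that fell and 7.57 for those that rose. The Fisher tests above count regions as independent, although all calls rest on the same 4 pairs. Their p values therefore overstate the evidence.

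The number of calls depended on the setting. The median region had a log2 ratio of -0.03 as deposited and 0.39 with libraries scaled to housekeeping promoters, where 2730 regions were higher and 195 lower; the split was 290 and 1046 with libraries centred on their median and 850 and 659 with quantile normalisation. Without Caki-1 9 regions were higher and 15 lower, without 2102EP 227 and 371, without VM-CUB-1 383 and 355, and without DU-145 310 and 1045. At 0.25 of the pseudocount 4 and 9 regions passed, and at 4 times 4 and 13; limma called 0 regions without the cell line block (1851 at an unadjusted p under 0.05) and 0 without the intensity trend (23853 at an unadjusted p under 0.05, against 26412 with it). Of the 20 named regions, 0 passed without the block or without the trend, 5 at 0.25 of the pseudocount, 6 at 4 times and 9 without Caki-1.

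**Figure D1:**
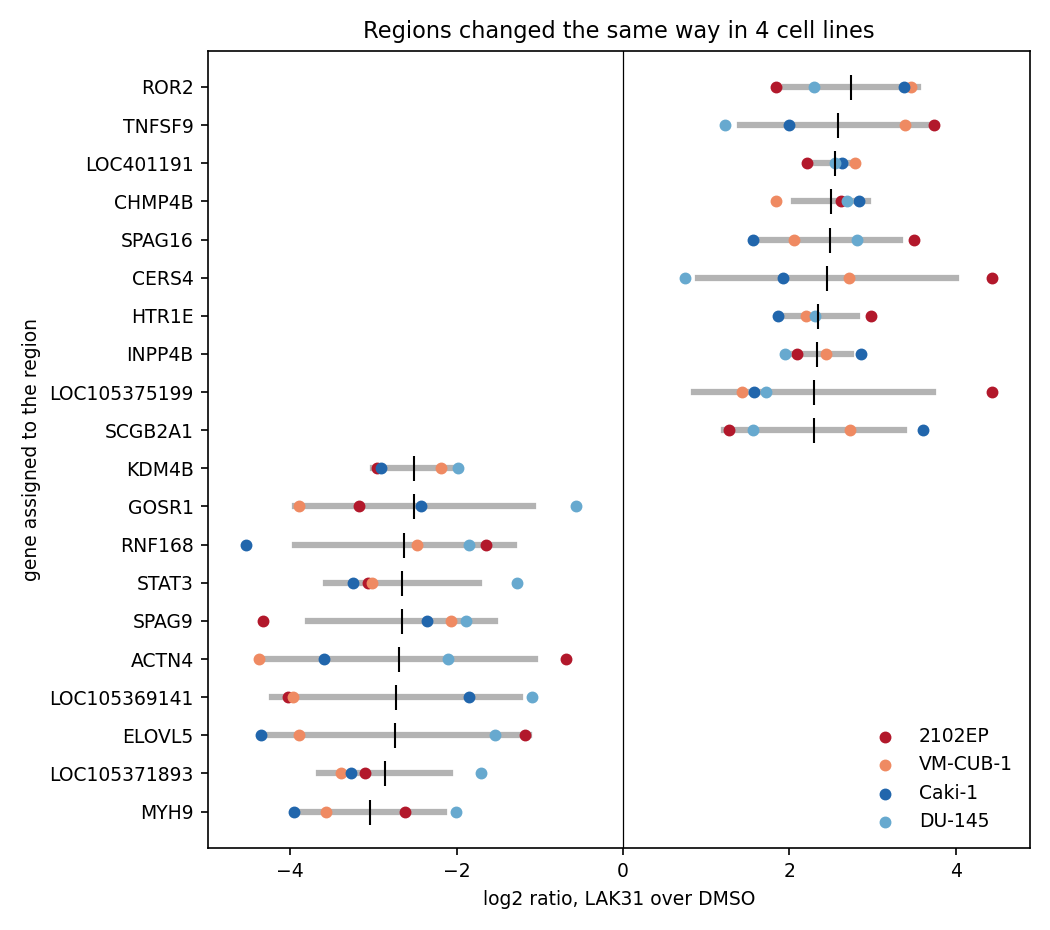
Log2 ratio of LAK31 over DMSO (x axis) for the 20 regions named across lines, with 1 dot per cell line, a black tick for the mean and a grey bar for the mean ± SD over the 4 lines. The means run from -3.04 at MYH9 to 2.75 at ROR2. The rule for naming took only regions with all 4 lines on the same side of 0.

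**Figure D2:**
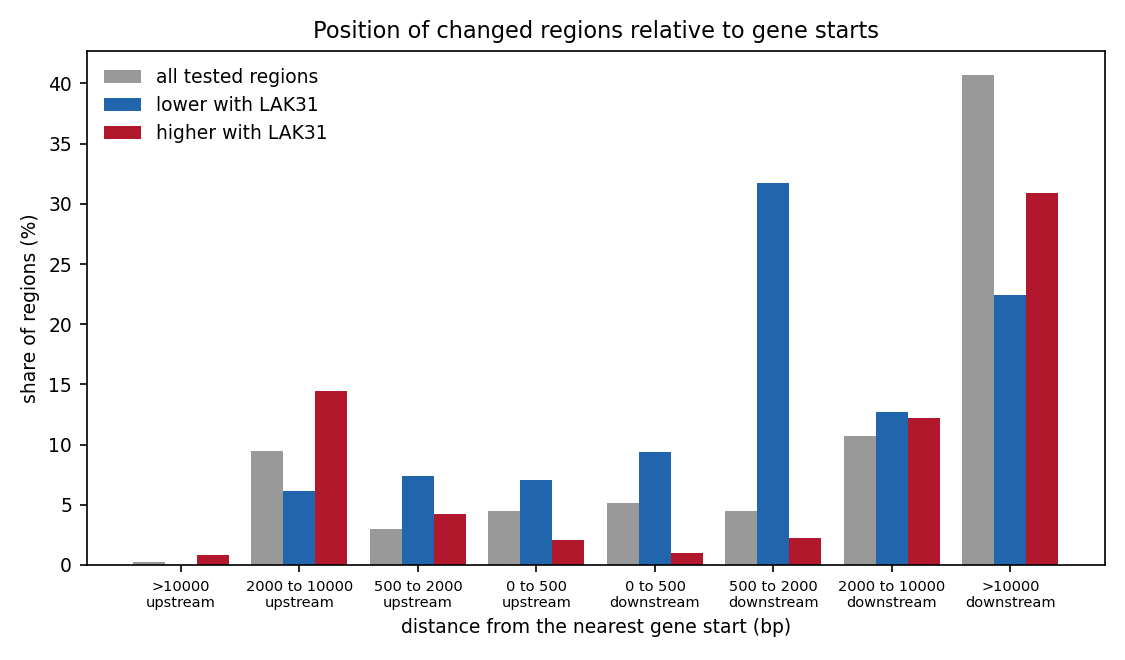
Share in percent (y axis) of all tested regions, of those that fell and of those that rose with LAK31 across the 4 lines, by the distance from the nearest gene start; regions with no gene named are left out, so the bars do not add up to the whole. The bars at 500 to 2000 bp downstream stand at 31.7% of the regions that fell, 4.48% of those tested and 2.25% of those that rose.

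By gene list, promoter regions of HDAC and bromodomain regulators were the only list past the set test across lines (29 regions, median log2 ratio -0.52, camera adjusted p = 0.0198, but adjusted p = 0.981 with an estimated correlation). With libraries centred on their median 3 further lists passed the set test (apoptosis, cell cycle and proliferation, and housekeeping), and with all regions of a gene 4 did (MYC and BET dependent, cell cycle and proliferation, heat shock and proteostasis, and housekeeping). On promoter regions as deposited, none of these further lists passed with an estimated correlation (camera adjusted p = 0.981 for each). Over all regions HDAC7 (-1.16, SE 0.29, adjusted p = 0.0393) and HDAC10 (-1.11, SE 0.28, adjusted p = 0.0460), which encode deacetylases, fell, and 27 members did not pass. Neither of these calls held at the other pseudocounts, with no filter, quantile normalisation, scaling to housekeeping promoters or peak height, without the block or the trend, or without 2102EP, VM-CUB-1 or Caki-1. That of HDAC10 was also lost without DU-145. Adjusted over the list alone, the acetyltransferase gene EP300 (-1.26, adjusted p = 0.00796) and the corepressor gene SIN3A (-1.10, adjusted p = 0.00818) fell as well, making 4 of 29; HDAC1 was at -0.27, turning to 0.05 with quantile normalisation and 0.14 with scaling to housekeeping promoters. In the other 17 lists limma called 0 of 348 regions over all regions (62 at an unadjusted p under 0.05), and no list had a member that rose. Of the members named by the rule, 4 passed with libraries centred on their median and 4 without DU-145, all of them lower. Adjusted over the list alone, 5 of 25 MYC and BET dependent regions fell (median -0.48, camera adjusted p = 0.213), among them CCND1 (-0.97) and HEXIM1 (-0.83). So did 3 of 22 apoptosis regions (median -0.48, adjusted p = 0.0864), namely HRK (-1.11), BID (-1.17) and XIAP (-1.02), and 3 of 29 cell cycle and proliferation regions (median -0.39, adjusted p = 0.0864), with TYMS at -0.95 and AURKB at -0.91. CDKN1B (-1.03) and TUBB3 (-0.93) fell among 29 HDAC inhibitor response and cell cycle arrest regions (median -0.28, adjusted p = 0.934), and KRT8 (-1.04) and TGFBI (-1.01) among 24 epithelial and mesenchymal regions (median -0.22, adjusted p = 0.934). A single region fell in the AP-1 and immediate early list (IER2, -0.90, of 22; median -0.21, adjusted p = 0.425), the neuronal and REST target list (STX1A, -1.21, of 34; median -0.31, adjusted p = 0.599) and the heat shock and proteostasis list (SQSTM1, -1.02, of 19; median -0.33, adjusted p = 0.129).

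In the remaining 9 lists limma called 0 of 151 regions (22 at an unadjusted p under 0.05). Their medians were -0.29 for pluripotency and embryonal carcinoma (20 regions, camera adjusted p = 0.392), -0.21 for urothelial (13, adjusted p = 0.392), -0.14 for renal (12, adjusted p = 0.599), -0.17 for prostate (11, adjusted p = 0.690) and -0.05 for germ cell and cancer testis (19, adjusted p = 0.123). They were -0.37 for trophoblast and germ layer (20, adjusted p = 0.616), -0.50 for immune and interferon (22, adjusted p = 0.137), -0.19 for metallothionein (9, adjusted p = 0.918) and -0.41 for housekeeping (28, adjusted p = 0.0937). The median over 17922 tested promoter regions was -0.31, and the set test, which compares a list with the other promoters, pointed up for 9 lists whose own medians were below 0. All 18 medians were below 0 as deposited and with libraries centred on their median, while 2 turned above 0 with quantile normalisation (germ cell and cancer testis at 0.07, AP-1 and immediate early at 0.11) and 13 did with scaling to housekeeping promoters. SOX2 had a mean of 0.63 (-0.47 in 2102EP, 0.75 in VM-CUB-1, 1.10 in Caki-1 and 1.14 in DU-145) and NANOG -0.59, with -3.01 in 2102EP and 0.26, 0.15 and 0.23 in the others; neither passed.

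Within single lines, where 1 library stood against 1 and nothing was tested, log2 ratios are given after removing the median of the pair (-0.33 in 2102EP, -0.05 in VM-CUB-1, 0.16 in DU-145, none in Caki-1). In 2102EP the promoter region of NANOG read 152 with DMSO and 17.3 with LAK31 (log2 ratio -2.68), that of the microRNA gene MIR135B 183 and 7.92 (-3.94) and that of CECR3 141 and 12.5 (-3.00). ACCSL read 1.78 and 37.1 (3.84), and CLEC4C, a lectin gene of dendritic cells, 10.0 and 115 (3.66). MYC was at -1.15, HEXIM1 at -0.67 and SOX2 at -0.14. Relative to the regions kept over all 8 libraries, SOX2 was at -0.29 as deposited and at 0.05 with quantile normalisation. Germ cell and cancer testis promoters had a median of 0.36, at percentile 100 of 10000 random lists matched on signal, and 16 of 24 lay above the median of all regions. AP-1 and immediate early promoters stood at percentile 95.2, trophoblast and germ layer promoters at 0.830, epithelial and mesenchymal promoters at 2.09 and HDAC and bromodomain regulators at 3.93. Matched on CpG islands as well, these 4 lists stood at 97.8, 1.23, 2.35 and 7.435. As deposited 22347 regions were at least 2-fold higher and 37479 lower, a split of 32886 and 21148 after removing the median, 35037 and 34638 with quantile normalisation and 53707 and 8277 with scaling to housekeeping promoters.

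In VM-CUB-1 the promoter of SCGB2A1 read 4.92 with DMSO and 41.8 with LAK31 (2.78), and that of the histone gene HIST1H3E 1.67 and 26.3 (3.14). TRIM34 was lower, at -3.44, and MIR133A1 was listed at 0 with LAK31. AP-1 and immediate early promoters stood at percentile 100 (median 0.29), with NR4A1 at 1.35 and FOS at 0.87, HDAC inhibitor response promoters at 99.7 and pluripotency promoters at 98.4. Trophoblast and germ layer promoters stood at percentile 2.53. In all 18287 regions were at least 2-fold higher and 24373 lower, and 22989 and 20169 with scaling to housekeeping promoters.

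In Caki-1 SCGB2A1 read 1.40 and 35.4 (3.61), while MIR4278 and the calcium-binding protein gene S100B were listed at 0 with DMSO and read 29.0 and 25.9 with LAK31. TMEM63B read 36.5 and 1.67 (-3.53) and PHF2, a histone demethylase gene, 27.1 and 1.00 (-3.45); HEXIM1 was at -1.51 and SOX2 at 1.10. AP-1 and immediate early promoters stood at percentile 99.8 and neuronal and REST target promoters at 97.9. MYC and BET dependent promoters stood at 2.80, heat shock promoters at 3.48 and apoptosis promoters at 3.71. Matched on CpG islands as well, these lists stood at 2.55, 2.345 and 5.47. Of all regions 28878 were at least 2-fold higher and 27386 lower, a split of 58340 and 11147 with scaling to housekeeping promoters.

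In DU-145 the sodium channel gene SCN3A read 1.27 with DMSO and 19.8 with LAK31 (2.72), and the glutathione transferase gene GSTA3 was listed at 0 and 15.6. CA9, a carbonic anhydrase gene induced by hypoxia, read 19.8 and 2.08 (-2.70), LINC00704 55.0 and 5.69 (-3.12), and SKI 62.4 and 11.9 (-2.40). SOX2 was at 0.98. Urothelial promoters stood at percentile 0.400, HDAC and bromodomain regulators at 2.97 and AP-1 and immediate early promoters at 35.8. As deposited 23781 regions were at least 2-fold higher and 8585 lower; the split was 17545 and 13030 after removing the median of the ratios, 14869 and 13199 with quantile normalisation, and 12326 and 19873 when each library was centred on its own median.

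Regions touching CpG islands had medians of -0.45 in 2102EP, -0.08 in VM-CUB-1, -0.49 in Caki-1 and -0.31 in DU-145, while regions outside genes and promoters stood at 0.24, 0.15, 0.30 and 0.15. Each line had its own DMSO library, so no control was shared between lines. Across regions, which are not independent replicates, Pearson's r between log2 ratios was 0.35 for VM-CUB-1 and Caki-1, 0.27 for Caki-1 and DU-145, 0.23 for 2102EP and DU-145, 0.19 for VM-CUB-1 and DU-145, 0.09 for 2102EP and Caki-1, and 0.04 for 2102EP and VM-CUB-1. VM-CUB-1 and Caki-1, the pair with the largest excess, shared 6090 regions at least 2-fold higher and 7710 lower, where independent lists would share 2742 and 3277. The smallest excess was in 2102EP and VM-CUB-1, with 2847 and 4186 against 2190.1 and 4021.6. All 4 lines had 499 regions at least 2-fold higher and 341 lower, such as those at ROR2 and STAT3, where independent lists would give 44.7 and 32.6. These 840 regions compare with 20 to 170 when the sign of 1 or more lines was turned. The ratios changed with signal, as given above, and none of these correlations and overlaps between lines was matched on it. A slope that lines share may therefore add to the correlations, the overlaps and the count of 840.

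The drugs in 2102EP were set beside each other to see which regions LAK31 shares with the other agents. At the promoter region of NANOG (hg38, chromosome 12, 7787521 to 7788019) the signal of 152 with DMSO was 17.3 with LAK31, 30.7 with romidepsin, 24.3 with quisinostat and 98.6 with MZ-1. After removing the median of each pair (-0.42 for LAK31, -0.80 for romidepsin, -1.21 for quisinostat and -0.65 for MZ-1), the log2 ratios were -2.39, -1.33, -1.21 and 0.05. The table of 4 lines has another pseudocount and another median of the pair, so its LAK31 value differs. ACCSL was at 3.50, 3.84 and 2.62 with LAK31, romidepsin and quisinostat and at 0.73 with MZ-1, and CLEC4C at 3.42, 2.61, 3.33 and 0.74. FASN, the fatty acid synthase gene, was at -2.43, -2.29, -1.19 and -0.98, and the tetraspanin gene CD9 at -2.05, -2.04, -1.71 and -0.49. MYC was at -1.05, -1.56, -0.88 and -0.24, and HEXIM1, a negative regulator of transcription elongation, at -0.53, -0.79 and -0.84 but 0.68 with MZ-1. As deposited HEXIM1 read 76.5 with DMSO and 78.4 with MZ-1, so its 0.68 comes from the removed median. The same holds for ACCSL and CLEC4C with MZ-1, at 0.08 and 0.09 as deposited.

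Germ cell and cancer testis promoters stood at percentile 100 with LAK31, romidepsin and quisinostat (medians 0.44, 0.48 and 0.69) and at 8.94 with MZ-1 (median -0.25). Relative to all regions, which only quantile normalisation among the scalings can change, the medians with it were 0.46, 0.52, 0.49 and -0.23 over the 23 of them kept across all libraries. Above the median of all regions lay 16 of 24 of them with LAK31, 14 of 21 with romidepsin, 18 of 23 with quisinostat and 5 of 18 with MZ-1. Examples picked after their values were seen are DAZL (1.36, 0.97, 1.61 and 0.05 in the same order of drugs), SYCP3 (1.28, 1.08, 0.94 and 0.09) and PAGE1 (1.97, 1.75, 1.72 and 0.44), with DMC1 at -0.73, -0.70, -0.96 and -0.64 as a member on the other side. Pluripotency promoters stood at percentiles 58.9, 5.34, 3.46 and 97.4, and AP-1 and immediate early promoters at 94.3, 95.3, 98.8 and 88.8. With LAK31 trophoblast and germ layer promoters stood at 1.58, epithelial and mesenchymal promoters at 0.870, cell cycle promoters at 3.27 and apoptosis promoters at 4.09, and with quisinostat housekeeping promoters at 96.5. Matched on CpG islands as well, these lists stood at 2.205, 0.78, 3.6, 5.44 and 97.07. With MZ-1 HDAC inhibitor response promoters stood at 98.6, neuronal and REST target promoters at 0.660 and metallothionein promoters at 1.29. Among genes named for a single drug, the nitric oxide synthase gene NOS3 read 1.67 with DMSO and 39.9 with romidepsin, TNFRSF9 76.2 and 3.29 with quisinostat, and the myogenic factor gene MYOD1 42.8 and 2.56 with MZ-1.

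Over all regions 6557 were at least 2-fold higher and 25250 lower with LAK31 as deposited, 5430 and 49272 with romidepsin, 1325 and 77123 with quisinostat, and 521 and 27384 with MZ-1. After removing the median the splits were 14545 and 9873, 17295 and 9248, 13023 and 6338, and 4089 and 2258; with scaling to housekeeping promoters they were 27252 and 3649, 39368 and 1147, 26361 and 1405, and 4480 and 1967. As deposited, all 3 of LAK31, romidepsin and quisinostat shared 1433 regions at least 2-fold higher, 133 of them also with MZ-1, and 19146 lower, 6196 of them also with MZ-1. After removing the medians they shared 9901 higher, 2222 of them also with MZ-1, and 2123 lower, 63 of them also with MZ-1. All drugs were set against the same DMSO library. In simulations, 3 unchanged libraries over 1 shared DMSO library had 276.1 regions in common that were higher and 273.7 that were lower (4 had 138.5 and 141.7). Independent lists of the observed sizes would share 5.75 and 5370.5 as deposited and 343.9 and 33.01 after removing the medians. Neither value takes in both the shared DMSO library and the changes, so part of the overlap may come from that library. The ratios also changed with signal. After removing the median of the pair, the lowest and highest signal quintiles had medians of 0.34 and -0.28 with LAK31. They had 0.34 and -0.37 with romidepsin, 0.37 and -0.39 with quisinostat, and 0.03 and -0.01 with MZ-1. The overlaps and the correlations below were not matched on signal, so this slope may add to them. A count by gene took 17012 genes whose promoter region had a mean signal at or above that of the median region. With all 3 drugs 34 were higher as deposited, such as ACCSL and RTBDN, and 3886 lower, such as VAMP2 and WSB2. After removing the medians 202 were higher and 246 lower. Genes that share a region were counted separately. Rises were more frequent at low signal (LAK31: 2834 in the lowest quintile, 145 in the highest), so leaving out weaker regions bears on this split. Pearson's r across regions, which are not independent replicates, was 0.777 for LAK31 and romidepsin, 0.767 for LAK31 and quisinostat and 0.860 for romidepsin and quisinostat, against 0.500 for simulated unchanged libraries that share the DMSO library. MZ-1 had 0.425, 0.414 and 0.443 with LAK31, romidepsin and quisinostat. The covariance was 0.545, 0.501 and 0.604 for the first 3 pairs and 0.177, 0.185 and 0.184 for those with MZ-1, against 0.131 simulated. The simulated r of 0.500 was fixed in advance, because all simulated libraries, DMSO included, were given the same noise. The simulated covariance follows from the spread of the MZ-1 ratios. A noisier DMSO library would raise both, so neither bounds what the shared library can give.

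**Figure D3:**
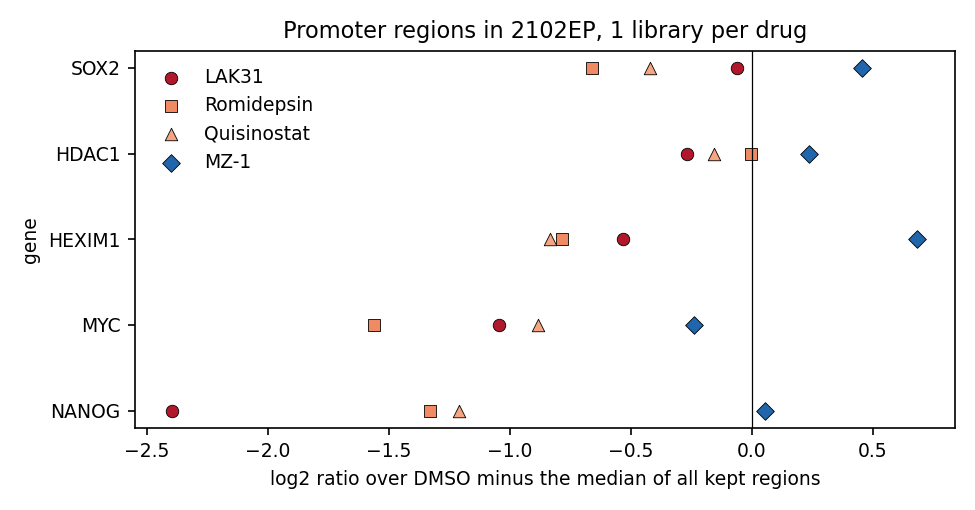
Log2 ratio of drug over DMSO minus the median of the pair (axis) at the promoter regions of 5 of the genes fixed beforehand in 2102EP, with 1 library per drug and no error bars. NANOG reads -2.39, -1.33, -1.21 and 0.05 with LAK31, romidepsin, quisinostat and MZ-1, and HEXIM1 -0.53, -0.79, -0.84 and 0.68. The signal of HEXIM1 itself was 76.5 with DMSO and 78.4 with MZ-1. HDAC1 turns above 0 with quantile normalisation for romidepsin (0.21) and quisinostat (0.06).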

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

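No test was made of any difference between lines in this part, since each line had 1 library per treatment; the items were picked because lines moved in opposite directions. The promoter region of IFIT2, an interferon-induced gene (hg38, chromosome 10, 89301959 to 89302333), had a log2 ratio of LAK31 over DMSO of -2.06 in VM-CUB-1 and 1.24 in 2102EP, with -2.06 in Caki-1 and 0.01 in DU-145. The averages listed for VM-CUB-1 and Caki-1 coincide at this region while their peak heights differ, and no peak was called there in 2102EP, whose signals were low. Over all regions the median log2 ratio was -0.33 in 2102EP and 0.16 in DU-145. The number of peaks called with LAK31 was 0.928 of that with DMSO in 2102EP and 1.20 of it in DU-145. Differences between the lines in these 3 measures were not tested, and no explanation was tested for them.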

How the results depend on the processing

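The tests with an estimated correlation and those on regions with a peak called in every line were chosen only after the results were seen; the other alternatives were set before. The number of regions called across the 4 lines was the result that depended most on the setting. The depth of the libraries is unknown and limits all values near the pseudocount, and the cause of each move below was not tested, except that a smaller or larger set of regions changes counts by construction.

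Across lines (711 regions higher, 1104 lower) the counts were 4 and 9 at 0.25 of the pseudocount, 4 and 13 at 4 times, 292 and 429 with no filter, and 253 and 372 with peak height. Centring on the median gave 290 higher, quantile normalisation 659 lower, and scaling to housekeeping promoters 2730 and 195. Without the cell line block (no replicate block, libraries not paired) limma called 0 and 0, with 1851 regions at an unadjusted p under 0.05, and without the intensity trend 0 and 0, with 23853. Leaving out 1 line gave 9 to 383 higher and 15 to 1045 lower, the lowest without Caki-1. Among 33356 regions with a peak called in every line 1089 were higher and 1872 lower. Autosomal regions alone gave 752 and 1161. Of the 1815 calls, 1134 were also called with libraries centred on their median, 1030 with quantile normalisation and 883 with scaling to housekeeping promoters. All 20 named regions fell short of the threshold without the block and without the trend, 15 at 0.25 of the pseudocount, 14 at 4 times, 11 without Caki-1, 5 without 2102EP and 3 with scaling to housekeeping promoters.

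Promoters that changed sign included HDAC1 with quantile normalisation (0.049); KRT7 (0.026), CDH16 (0.077), HDAC1 (0.14), MT1F (0.20) and MT1G (0.013) with scaling to housekeeping promoters. Leaving out 1 line gave MT1F values from -0.58 to 0.245, highest without 2102EP, and CA9 values from -0.73 to 0.29, highest without DU-145. None of these had passed the test. Promoters that passed only in an alternative were all lower: 4 with libraries centred on their median, 4 without DU-145 and 18 of 40 among regions with a peak called in every line. Of 18 lists, 14 kept their side of the threshold when all regions of a gene were used and 15 with libraries centred on their median, the other 4 and 3 now passing; 17 did with an estimated correlation, where HDAC and bromodomain regulators no longer passed. In DMSO libraries alone the prostate list in DU-145 had a median of -0.16, and the other 3 lineage lists kept their sign.

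Within lines, 4 times the pseudocount gave 13056 regions higher in 2102EP, 6838 higher and 13129 lower in VM-CUB-1, 12849 higher in Caki-1, and 9995 and 2227 in DU-145. At 0.25 of it there were 12992 lower in DU-145, and no filter 34751 higher in 2102EP and 14228 lower in DU-145. Scaling to housekeeping promoters gave 53707 and 8277 in 2102EP and 58340 and 11147 in Caki-1. Quantile normalisation gave 35037 higher in 2102EP and 14869 and 13199 in DU-145, and centring on the median 12326 and 19873 in DU-145.

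For the drugs in 2102EP (LAK31, romidepsin, quisinostat and MZ-1 in that order), 4 times the pseudocount gave 1357, 1286, 256 and 133 regions higher and 9145, 21610, 36492 and 3709 lower; at 0.25 of it there were 889 higher with MZ-1. No filter gave 15421, 11412, 4467 and 1983 higher. Centring on the median gave 12346, 14115, 10153 and 3629 higher and 12274, 13815, 10081 and 2628 lower. With quantile normalisation 12467, 8825 and 1688 were higher with romidepsin, quisinostat and MZ-1, and 11473, 12378, 11791 and 1746 lower with the 4 drugs. Scaling to housekeeping promoters gave 27252, 39368, 26361 and 4480 higher and 3649, 1147, 1405 and 1967 lower.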

Other observations

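Of the tests in this part, the count of splits of the libraries was chosen only after the result was seen. Several promoters of lineage and cell cycle genes lay on opposite sides of 0 in different lines with LAK31; they were picked after their values were seen, had 1 library against 1, and were not tested for a difference. GRHL3, a transcription factor gene of surface epithelia, read 102 with DMSO and 16.2 with LAK31 in 2102EP (log2 ratio after removing the median -2.20) and 14.9 and 52.4 in VM-CUB-1 (1.76). LHX1, a gene of kidney development, read 77.4 and 21.8 in 2102EP (-1.42) and 12.5 and 52.1 in Caki-1 (1.93). The cyclin gene CCND2 was at -1.11 in 2102EP and at 1.39 in VM-CUB-1 and 1.38 in DU-145. In Caki-1 the promoter of PAX8, open in that line with DMSO, read 161.5 and 38.4 (-2.03), while that of EMX2, another gene of kidney development, read 2.89 and 18.2 (2.14).

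The shrunken fold changes in the authors' deposited table, taken as log2, were smaller in size than the ratios computed here at the regions of MYH9 and ROR2. In the authors' deposited table MYH9 stood at -0.77 in 2102EP, -1.44 in VM-CUB-1, -1.51 in Caki-1 and -0.89 in DU-145, and ROR2 at 0.41, 1.39, 1.09 and 0.73. Values of 1 or more and of -1 or less in the authors' deposited table numbered 56 and 130 in 2102EP, 34 and 334 in VM-CUB-1, 34 and 914 in Caki-1, and 1 and 6 in DU-145. Across regions, which are not independent replicates, they correlated with the ratios computed here at 0.855, 0.845, 0.896 and 0.704.

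For the regions called across the 4 lines there are 35 splits of the 8 libraries into 4 and 4, of which 3 set whole lines against each other and could not be fitted. Only the 8 splits that part both libraries of every line are comparable with the real one; among them 1 split, the real one, gave 1815 calls and the highest other gave 0. These 8 splits are too few for a share under 0.05. The remaining splits part fewer lines, and the highest of them gave 240.

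Regions 500 to 2000 bp downstream of gene starts, such as those in MYH9 and STAT3, were lower with LAK31 than regions as far upstream with the same signal, by -0.25 in 2102EP, -0.18 in VM-CUB-1, -0.32 in Caki-1 and -0.18 in DU-145 (log2). A compressed or noisier LAK31 library would lower both sides alike; the smallest of these differences was -0.177, short of the bound of -0.2 set before, so this explanation was not excluded and cannot be told apart from an effect of the drug. The base composition of CpG islands stays a candidate explanation: among regions that touch no island the difference was -0.177, -0.110, -0.186 and -0.0436 in the same order of lines, and the last of these met the bound set before for this cause (above -0.1 in at least 1 line); among regions that touch one, where composition was neither measured nor matched, it was -0.126, -0.166, -0.283 and -0.114. As a hypothesis, HDAC inhibition may be behind it, but in ratios to the MZ-1 library, which leave DMSO out, the smallest difference of LAK31, romidepsin and quisinostat was -0.174 and the largest -0.247, which again left the matter open. MZ-1 over DMSO gave -0.0439.

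Regions called with LAK31 in the 3 lines other than 2102EP (227 higher, 371 lower) were looked up in 2102EP, whose libraries had no part in the calls. Of the lower ones, 108 were in the table of drugs, where they read below regions of the same signal by -0.90 with LAK31, -0.61 with romidepsin and -0.41 with quisinostat, against 0.08 with MZ-1; the 146 higher ones read 0.67, 1.02, 0.87 and -0.09. In ratios to MZ-1, which leave the DMSO library out, the smallest difference at the 108 lower ones was -0.585 and the largest -0.846. Both the 108 and the 146 were in a table merged from peaks of the 2102EP libraries, DMSO and MZ-1 among them. The signal in 2102EP therefore helped to choose them, and ratios to MZ-1 do not remove this choice. A DMSO library of 2102EP that reads high at the lower regions was thus not excluded as an explanation. A shared effect of HDAC inhibitors on these regions is a hypothesis that may be followed up; other technical explanations were not tested. With all 371 taken in the table of 4 lines, the median in 2102EP was -0.41. The median of all regions was -0.19, and 56.6% of the 371 lay below it. All 227 higher ones had a median of 0.49 there, and 23.3% of them lay below that of all regions.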
